A study of Mus musculus with 5 samples.

How the data were processed

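Total RNA from flash-frozen dorsolateral prostate was made into TruSeq Stranded Total RNA libraries, per the labels' protocols, from 3 control mice and 2 mice labelled Ghr deletion. The submitters' processing notes name bcl2fastq 2.20.422, STAR 2.5.3a and RSEM 1.3.0 with the GRCm38 build. The order of these steps, the annotation release and the strand setting are not given in the sources used here. The authors deposited RSEM gene tables, 1 per sample. Per the file headers, these hold expected counts, in which a read that fits several genes is shared out by a model, so genes with near-identical copies are uncertain. Per the file headers they also hold TPM, which is the expected count divided by effective length and scaled to the library, and the effective length itself, which the authors deposited as a value per gene and sample.

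Groups and replicate numbers came from the sample titles. Expected counts were rounded to whole numbers, filtered with filterByExpr by group, and scaled by TMM. Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment at 0.05. No removal step for abundant RNA is stated in the sources used here. The counts hold abundant RNA such as Rn7s1, and this lowers the share left for other genes. Abundance is given as CPM on the TMM-scaled library size. The standard error of a log2 fold change was taken from the size of the change and its F statistic, and the 95% interval from the t distribution with the test's degrees of freedom. Positive values are higher in the libraries labelled Ghr deletion. An exact test of 1 value over 3 against 2 samples cannot give a two-sided p below 0.2, so p-values come from the model across genes. Symbols were matched for 99.5% of gene identifiers, and coordinates are from GENCODE release M21 on GRCm38, which holds 99.6% of them.

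Before the data were examined, 30 gene lists, the tests, the rule for named genes and most alternatives were fixed. Camera in limma 3.58.1 tested the 29 lists with at least 3 tested members, with a preset correlation of 0.01. An estimated correlation and fry were alternatives, and neither called any list. The named genes are Ghr and Igf1, the members of the growth hormone list that were called (0), and the called genes with the largest changes in each direction. Where a direction had fewer than 5 such genes, the rule took the 5 with the smallest p among genes with an average log2 CPM of at least 1 and no overlap between groups, leaving out predicted genes and pseudogenes. Of each list described, 2 to 4 members with the smallest p were named, except that 1 such member is not reported here. Members named beyond these, such as Svs2, Pate4 and Spink1, were chosen after their values were seen.

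The alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, a robust prior, limma-trend on TPM with a pseudocount of 1 or 0.1, effective lengths as offsets, the 20 most abundant genes left out, each library left out in turn, and the replicate number as a block. Additions made after seeing the data were leaving out control replicates 1 and 2 together, a covariate made from 4 seminal vesicle genes, and protein-coding genes only. Each of these 4 genes, Svs1, Svs3a, Svs3b and Svs6, was lower in both libraries labelled Ghr deletion than in each control. The covariate therefore overlaps with the group term, so directions and calls under it are uncertain. Scaling by library size only moved the median log2 fold change of all genes to 0.58, and TPM moved it to 0.87 with a pseudocount of 1 and 1.33 with 0.1, so directions under these are relative to that shift. Genes that match other transcripts were aligned with BLAST+ 2.17.0.

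The edgeR step was tested on simulated counts with 200 changed genes over 18330 genes. It gave 7 calls among unchanged genes and 0 calls in the wrong direction. Camera recovered a simulated set of 12 genes raised 2-fold while calling 0 of 19 unchanged sets. Each gene was drawn independently, so the simulated sets do not show how the preset correlation performs on lists whose members vary together. Depth ran from 19517831 to 41553558 expected counts per library. The floors used for genes at 0 are 3 counts per library and cover counting error only.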

Results

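The series measured gene expression in the dorsolateral prostate of 3-month-old male mice by sequencing total RNA. The growth hormone receptor gene Ghr carried loxP-flanked alleles in every mouse. The 3 control samples came from mice without Cre, and 2 samples came from mice that also carried a tamoxifen-inducible Cre recombinase at the ROSA26 locus. Both groups received tamoxifen at 250 mg/kg daily for 5 days, and tissue was taken 1 month after the last dose. The labels call the samples biological replicates. The 3 control libraries held 19517831, 29705618 and 41553558 expected counts (replicates 1 to 3), and the libraries labelled Ghr deletion held 31740687 and 32782683 (replicates 1 and 2). Of 51912 genes listed, 18590 passed the filter on low counts and were tested.

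The comparison asks how loss of the growth hormone receptor changes expression in the prostate, so Ghr itself was examined first. Ghr (ENSMUSG00000055737, GRCm38 chromosome 15, 3317760 to 3583492) was not lower in the libraries labelled Ghr deletion. Its abundance was 10.1, 11.8 and 13.2 CPM in the controls and 21.5 and 10.2 CPM in the libraries labelled Ghr deletion, or 11.7 ± 1.52 CPM (SD, n = 3) against 15.9 ± 7.97 CPM (SD, n = 2). The log2 fold change of the deletion-labelled over the control libraries was 0.44 (SE 0.35, 95% confidence interval -0.42 to 1.3), with an adjusted p of 0.874 by edgeR's quasi-likelihood test. Without Ghr deletion replicate 1 the value was -0.20, and without Ghr deletion replicate 2 it was 0.88. The counts are summed over the whole gene, and the labels used here do not say which exon was flanked, so a deletion that leaves the rest of the transcript in place need not lower this value. Because Ghr, counted over the whole gene, does not show whether it was deleted, every direction below is that of the libraries labelled Ghr deletion.

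Genes known to act downstream of the receptor did not pass the test. Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042), which encodes the growth factor that growth hormone induces in many tissues, had 61.2, 20.7 and 58.9 CPM in the controls and 89.8 and 43.8 CPM in the libraries labelled Ghr deletion (log2 fold change 0.51, SE 0.54, adjusted p = 0.88 by edgeR). Its value without Ghr deletion replicate 1 was -0.10. Of 13 tested genes of the growth hormone receptor signalling list, 0 passed over all genes and 0 passed when adjusted over the list alone. Stat5a and Stat5b, the transcription factors activated by the receptor, had log2 fold changes of -1.06 (SE 0.52) and -0.90 (SE 0.37), and both stayed below the median of all genes on the TPM scale. Stat5a had 89.0, 194 and 61.6 CPM in the controls and 62.5 and 47.8 CPM in the libraries labelled Ghr deletion. Stat5b had 105, 128, 58.5, 58.9 and 45.3 CPM in that order. For both genes, control replicate 3 lay between the libraries labelled Ghr deletion. Of 16 tested genes of the insulin-like growth factor axis, 0 passed either way. Igf1r, the receptor for Igf1, had a log2 fold change of -0.53 (SE 0.27) and lay above the median of all genes on log2(TPM + 1), by 0.056, and Igfbp7, a binding protein, had 0.81 (SE 0.45). Neither list was called by camera, with an adjusted p of 0.655 for both.

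**Figure D1:**
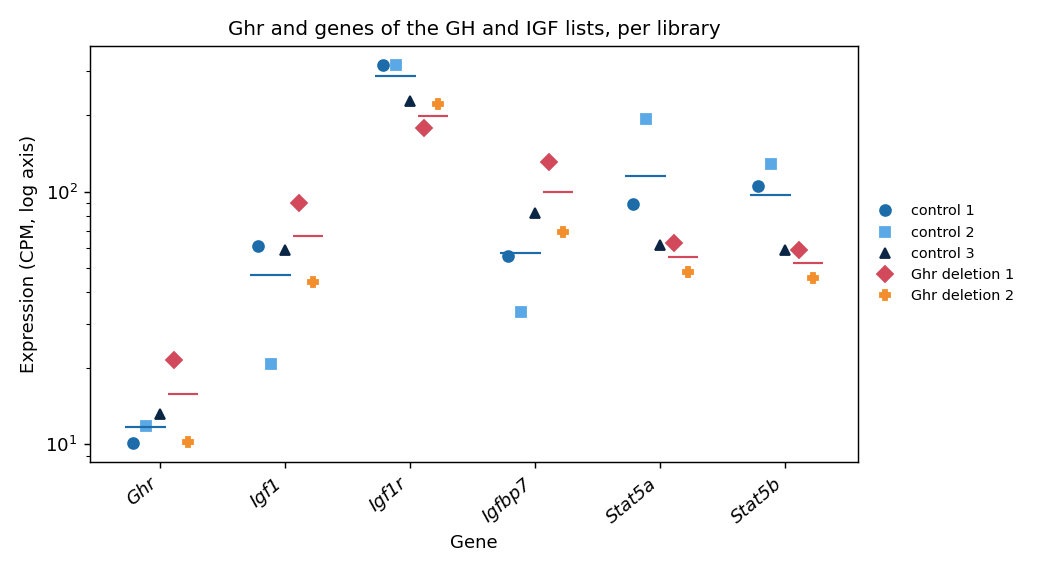
Abundance of Ghr, Igf1 and 4 members of the growth hormone and insulin-like growth factor lists on a log axis in CPM, with 1 point per library and a horizontal line at each group mean. Ghr spans 10.1 to 13.2 CPM in the 3 controls and 10.2 to 21.5 CPM in the 2 libraries labelled Ghr deletion, and no gene shown passed the test.

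Across all genes, 0 were higher and 0 were lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 792 genes, 216 higher and 576 lower, where 930 would be expected by chance. DESeq2 called 20 genes higher and 59 lower, with 1306 at an unadjusted p under 0.05, and limma-voom called 0 and 0. The 2 groups did not overlap in 2004 genes that were higher (10.8%) and 2333 that were lower (12.5%), where chance gives 10% in each direction. The biological coefficient of variation was 42.7%. Leaving out control replicate 3 gave 15 genes higher and 33 lower, and leaving out any other single library gave 0 and 0. On simulated counts with the spread of these libraries, the test over 18330 genes called 1 of 50 genes changed 2-fold, 18 of 50 changed 4-fold, 45 of 50 changed 8-fold and 49 of 50 changed 16-fold. The changed genes were drawn from those with a mean of at least 2 CPM. Each gene varied independently, so differences that many genes share between control libraries were not simulated. These shares may therefore be too high for the real libraries.

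The smallest adjusted p was 0.0935, for Eif3j2 (ENSMUSG00000043424, chromosome 18, 43475418 to 43477796), a near-identical relative of the translation initiation factor gene Eif3j1. Eif3j2 had 1.79, 1.54 and 1.83 CPM in the controls and 22.1 and 19.8 CPM in the libraries labelled Ghr deletion, a 12.1-fold difference (log2 fold change 3.60, SE 0.23). Its sequence matches Eif3j1 at 99.4% over 2379 bases, so its counts depend on how reads were shared between the genes and are uncertain. Eif3j2 passed the threshold with no filter on low counts, by DESeq2, by limma-trend on TPM, with the replicate block and without control replicate 3 and its adjusted p over all settings ran from 2.6e-29 with DESeq2 to 1 with the seminal vesicle covariate.

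The other genes with the smallest p did not pass, with an adjusted p of 0.874 for each by edgeR. On the higher side, Cfb, complement factor B, had 5.44 ± 0.74 CPM (SD, n = 3) in controls and 18.6 ± 6.81 CPM (SD, n = 2) in the libraries labelled Ghr deletion, and Itgb6, an epithelial integrin subunit, had 12.0 ± 2.44 and 33.8 ± 9.62 CPM. Cdc14b, a phosphatase, had 4.83 ± 0.636 and 14.4 ± 5.64 CPM, and Psmc3ip, a meiotic recombination factor, had 1.52 ± 0.587 and 6.79 ± 1.96 CPM. Their log2 fold changes were 1.77, 1.49, 1.57 and 2.16. On the lower side, Entpd2, an ectonucleotidase, had 28.6 ± 3.22 and 13.3 ± 0.789 CPM, and Dok1, a docking protein of tyrosine kinases, had 9.98 ± 0.979 and 4.55 ± 0.46 CPM. Id3, a transcriptional inhibitor, had 53.5 ± 24.8 and 10.6 ± 1.26 CPM, Rnase1, a secreted ribonuclease, had 33.2 ± 21.3 and 3.12 ± 0.792 CPM, and Apob, an apolipoprotein made mainly in liver and intestine, had 4.30 ± 1.07 and 0.788 ± 0.329 CPM. DESeq2 called each of these genes, and without control replicate 3 edgeR called Id3.

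**Figure D2:**
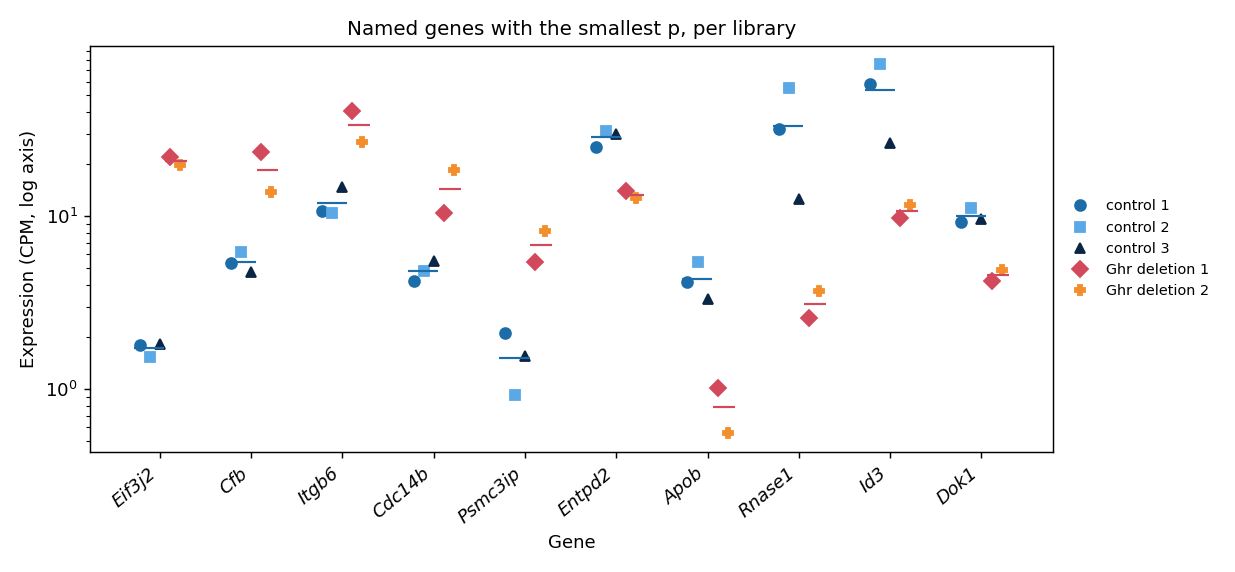
Abundance of the 10 named genes with the smallest p on a log axis in CPM, with 1 point per library and a horizontal line at each group mean. Both libraries labelled Ghr deletion lie outside the 3 controls for each gene, which was a condition for naming them, and none passed the adjusted threshold.

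Of 8 genes of the seminal vesicle, an androgen-dependent gland next to the prostate, 6 were lower in both libraries labelled Ghr deletion than in each control. For 5 of these 6, control replicate 3 lay nearer in CPM to both of those libraries than to either other control, and Svs5 was the exception, with 148704, 76179 and 56115 CPM in the controls and 12797 and 32765 CPM in the libraries labelled Ghr deletion. The list was called by camera (adjusted p = 4.3e-08, median log2 fold change -7.48), and with an estimated correlation its adjusted p was 0.553. Without control replicate 1 the median was -6.40. Together the 8 genes took 37.5%, 15.4% and 25.6% of counts in the controls and 14.6% and 22.2% in the libraries labelled Ghr deletion. Svs1, a secretory protein, had 32915 and 22520 CPM in control replicates 1 and 2, 58.6 CPM in control replicate 3, and 0.0454 and 7.90 CPM in the libraries labelled Ghr deletion. Svs3a had 13509, 4883, 22.4, 0.113 and 2.67 CPM in the same order, Svs3b had 9009, 4293, 38.8, 0.499 and 2.60 CPM, and Svs6 had 19949, 8915, 70.2, 5.94 and 10.6 CPM. Of 8 members, 5 passed by edgeR when adjusted over the list alone and 0 over all genes. DESeq2 called 5 over all genes, with an adjusted p of 7e-06 for Svs3b, 7.3e-05 for Svs6, 0.000108 for Svs3a, 0.000887 for Svs1 and 0.00179 for Svs4, and edgeR called Svs6 without control replicate 3 (adjusted p = 0.0465). The other members, Svs2 (log2 fold change 0.12, SE 0.97) and Pate4 (0.25, SE 0.76), were not lower, and they ranged from 47338 to 140510 CPM and from 10520 to 33092 CPM over the 5 libraries. Without control replicates 1 and 2 together, a comparison chosen after seeing the data, the median was -2.19, and the adjusted p was 2.8e-15 with the preset correlation and 0.884 with an estimated correlation. That comparison has 1 control library, so it holds no spread between controls and assumes that this library varies like the others.

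Markers of distal luminal prostate epithelium were also uneven among the controls. Of 12 tested genes 0 passed, also when adjusted over the list alone, and camera gave an adjusted p of 0.0551 (lower, median log2 fold change -1.68), and 0.914 with an estimated correlation. With the preset correlation the list passed under several settings, among them upper-quartile factors (0.0495), no low-count filter (0.0376), library size only (0.000224), and without control replicate 3 (0.0103) or Ghr deletion replicate 2 (0.0265). Its adjusted p was 0.349 with limma-voom, 0.108 with a filter at CPM 1, 0.154 without control replicate 1 and 0.457 without control replicate 2, where the median was -0.28. With the seminal vesicle covariate, chosen after seeing the data, the list was higher (adjusted p = 0.00162). Each gene of that covariate separates the groups, so this direction is uncertain. Msmb, a prostate secretory protein, had 11.1, 112 and 0.0441 CPM in the controls and 0 and 0.429 CPM in the libraries labelled Ghr deletion, and Azgp1 had 2.28, 27.8, 0.926, 0.318 and 1.26 CPM. Epcam, an epithelial adhesion molecule, had a log2 fold change of 0.52 (SE 0.25), and Cldn3, a tight junction protein, had -0.78 (SE 0.20). Of 8 tested proximal luminal genes, 6 passed when adjusted over the list alone and 0 over all genes, 3 of them higher and 3 lower, and camera gave an adjusted p of 0.839. Krt4 (log2 fold change 2.26) and Wfdc2 (1.56) lay on the higher side and Krt7 (-1.60) on the lower side, where Krt7 had 43.9 and 37.0 CPM in control replicates 1 and 2 and 12.6 CPM in control replicate 3.

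**Figure D3:**
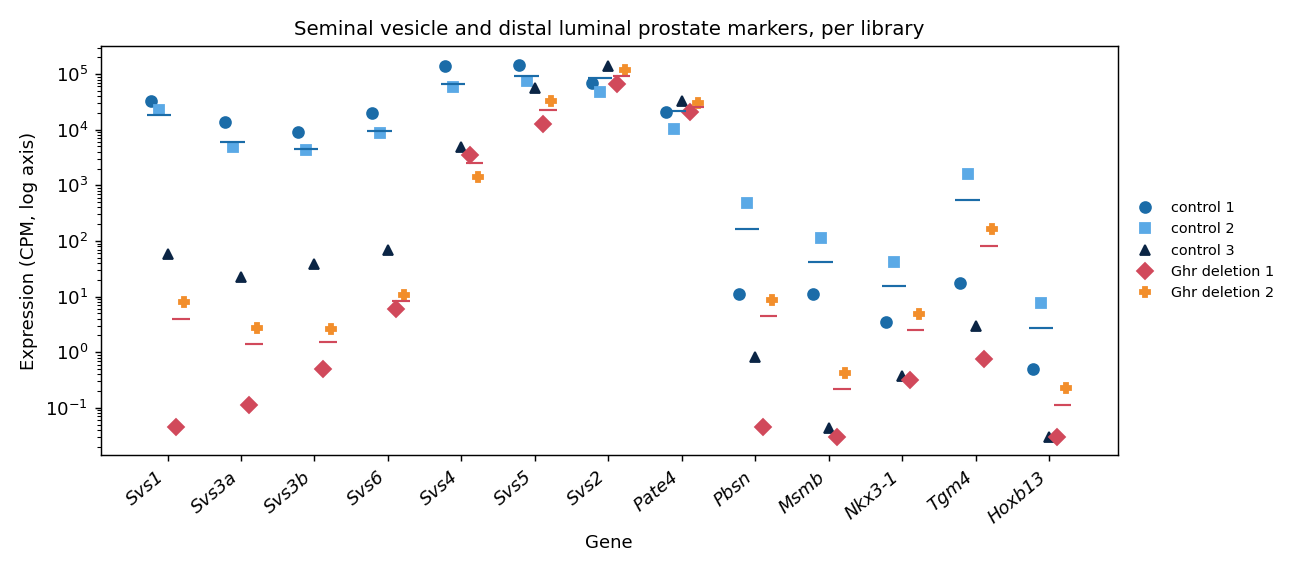
Abundance of 8 seminal vesicle genes and 5 distal luminal prostate genes on a log axis in CPM, with 1 point per library, a horizontal line at each group mean, and values below 0.03 CPM drawn at 0.03. Control replicates 1 and 2 hold Svs1 at 32915 and 22520 CPM, whereas control replicate 3 holds it at 58.6 CPM and the libraries labelled Ghr deletion at 0.0454 and 7.90 CPM.

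Camera called 4 further lists, and each call was lost with an estimated correlation. Adipocyte genes were higher (adjusted p = 3.6e-08, median log2 fold change 2.30, or 2.10 with Lep at its lower bound), with an adjusted p of 0.391 with an estimated correlation. The median was 1.19 without Ghr deletion replicate 1 and 2.95 without Ghr deletion replicate 2. Their levels were low. Adipoq, a fat-cell hormone, had 0, 0.103 and 0.11 CPM in the controls and 1.23 and 0.328 CPM in the libraries labelled Ghr deletion, and Lep, which encodes leptin, had 0 counts in each control and was at least 3.06-fold higher against a floor of 3 counts per library. Cfd had 0.432, 0.771, 0.662, 4.97 and 0.984 CPM, and Cidec 0, 0, 0.198, 1.2 and 0.681 CPM. Of 8 tested members 0 passed when adjusted over the list alone.

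Basal epithelial genes were lower (camera adjusted p = 0.00316, median -0.46), with an adjusted p of 0.914 with an estimated correlation. Krt17, a basal keratin, had a log2 fold change of -1.71 (SE 0.48), and Krt5 had -0.61 (SE 0.25). Proliferation genes were higher (camera adjusted p = 0.00501, median 0.54), with an adjusted p of 0.914 with an estimated correlation. Tyms, an enzyme of thymidylate synthesis, had 0.57 (SE 0.35) and Bub1, a spindle checkpoint kinase, had 0.97 (SE 0.73). Mitochondrially encoded genes were lower (camera adjusted p = 0.00501, median -0.53), with an adjusted p of 0.914 with an estimated correlation, and were called higher on log2(TPM + 1) (adjusted p = 0.0394). Of these, mt-Nd3 had -0.86 (SE 0.22), and mt-Atp6 had -0.50 (SE 0.25) and lay above the median of all genes on log2(TPM + 1), by 0.14. In these 3 lists 0 members passed by edgeR when adjusted over the list alone, and DESeq2 called 1 member over all genes, mt-Nd3 (adjusted p = 0.00644). Without control replicates 1 and 2 together, which leaves 1 control library, the adjusted p was 0.0693 for basal, 0.512 for proliferation, 0.512 for mitochondrially encoded and 3.4e-05 for adipocyte genes, the last being 0.884 with an estimated correlation. The medians were then -0.21, -0.024, -0.050 and 1.94. With the seminal vesicle covariate the adjusted p was 0.466 for basal (median -0.016), 0.0738 for mitochondrially encoded (median 0.25) and 0.137 for adipocyte genes (median 1.13). Proliferation genes were then called lower (adjusted p = 5.9e-06, median -0.77). The genes of the covariate each separate the groups, so these values are uncertain. Without control replicate 2 the adjusted p for proliferation was 0.525 and for mitochondrially encoded genes 0.304, with medians of 0.22 and -0.24. Without Ghr deletion replicate 1 these were 0.601 and 0.274, with medians of -0.26 and -0.36. The proliferation median was 0.91 without control replicate 3 and also without Ghr deletion replicate 2, and without Ghr deletion replicate 2 the basal value was 0.0553, with a median of -0.50. Leaving out control replicate 3 raised the number of lists called from 5 to 11, and leaving out Ghr deletion replicate 2 raised it to 8.

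The remaining lists were not called by camera in the main test and had 0 members past the threshold over all genes by edgeR. For androgen response the adjusted p was 0.654, and of 19 tested genes 0 passed when adjusted over the list alone, with Homer2 at -0.85 (SE 0.25). The adjusted p was 0.0937 for fibroblasts and matrix, 0.176 for smooth muscle, 0.359 for endothelium, 0.302 for myeloid cells, 0.0551 for T and B cells, 0.825 for urothelium, 0.655 for skeletal muscle, 0.268 for erythroid cells, 0.655 for nerve and Schwann cells and 0.655 for neuroendocrine cells. It was 0.654 for prolactin and related receptors, 0.947 for cholesterol synthesis, 0.885 for fatty acid synthesis, 0.607 for the unfolded protein and amino acid response, 0.268 for interferon response, 0.655 for immediate early genes, 0.359 for p53 targets, 0.268 for the nuclear-encoded respiratory chain and 0.947 for the circadian clock. In each of these 0 members passed when adjusted over the list alone. T and B cell genes, on the lower side in the main test, had an adjusted p of 0.914 with an estimated correlation. With the preset correlation they were called lower under several settings, among them upper-quartile factors (adjusted p = 0.0458), library size only (0.000224), no low-count filter (0.0186), the 20 most abundant genes left out (0.0136), and without control replicate 3 (0.000165) or Ghr deletion replicate 1 (0.000753). Their adjusted p was 0.682 with limma-voom, 0.369 with a filter at CPM 1, 0.654 without control replicate 1, 0.371 without control replicate 2 and 0.303 without Ghr deletion replicate 2. They were called higher with the seminal vesicle covariate (3e-06), whose genes each separate the groups. Leaving out 1 library also called other lists of this group with the preset correlation. Fibroblast and matrix genes were called higher without control replicate 3 (0.0103) or Ghr deletion replicate 2 (3.6e-08), and myeloid genes higher without control replicate 1 (0.0111) or Ghr deletion replicate 2 (0.000773). Smooth muscle genes were called higher without control replicate 3 (0.00785) or Ghr deletion replicate 1 (0.032), endothelial genes higher without Ghr deletion replicate 2 (0.0336), and nerve and Schwann cell genes higher without control replicate 2 (0.0122). Erythroid (0.00785) and interferon response genes (0.0161) were called lower without control replicate 3. An estimated correlation was not run with 1 library left out. In the main test it gave an adjusted p of 0.946 for nerve and Schwann cells and 0.914 for each other list called when 1 library was left out. Without control replicates 1 and 2 together, smooth muscle genes were called lower (0.00207), and T and B cell (0.00131), erythroid (0.00131), nerve and Schwann cell (0.003) and interferon response genes (0.00661) higher, and each of these 5 had an adjusted p of 0.884 with an estimated correlation. With the seminal vesicle covariate, fibroblast and matrix (8e-05), smooth muscle (0.0103), skeletal muscle (0.0339) and p53 target genes (0.0442) were called lower, and erythroid (3e-06), interferon response (3.9e-05), urothelium (0.000586), nerve and Schwann cell (0.00162) and cholesterol synthesis genes (0.0116) higher. With library size only, nerve and Schwann cell genes were called lower (0.0436), and on log2(TPM + 1) they (0.000527) and neuroendocrine genes (0.00142) were. The ventral prostate list had 2 tested members, too few for camera, and 1 of them, Spink1, passed by edgeR when adjusted over the list alone and by DESeq2 over all genes (adjusted p = 0.0135), with 2937, 892, 1.43, 0 and 0.53 CPM in the order given for Svs1. The other tested member, Sbp, lay on the higher side in the main test and did not pass when adjusted over the list alone.

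The libraries also differed in composition. The signal recognition particle RNA genes Rn7s1 and Rn7s2 took 9.23%, 32.9% and 9.49% of counts in the controls and 3.76% and 6.35% in the libraries labelled Ghr deletion. Mitochondrial ribosomal RNA took 1.78%, 9.91%, 2.31%, 2.52% and 3.49%, and protein-coding genes 85.2%, 48.5%, 83.5%, 88.3% and 84.2%, in the same order. Across genes, the Spearman correlation of log2 CPM was 0.978 and 0.981 between control replicate 3 and the libraries labelled Ghr deletion, but 0.95 and 0.915 between control replicate 3 and control replicates 1 and 2. Genes are not independent replicates in these correlations.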

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

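Leaving out control replicates 1 and 2 together, the seminal vesicle covariate and protein-coding genes only were chosen after seeing the data; the other settings were planned. The count of 0 higher and 0 lower genes was the same under RLE and upper-quartile factors, library size only, a filter at CPM 1, limma-voom, a robust prior, effective-length offsets, the 20 most abundant genes left out and the 3 added settings. With no low-count filter 2 genes were higher. DESeq2 gave 20 higher and 59 lower. Limma-trend gave 2234 higher and 60 lower on log2(TPM + 1), and 686 and 47 on log2(TPM + 0.1), where the median of all genes had also shifted upwards. Leaving out 1 library gave from 0 to 15 genes higher and from 0 to 33 lower, the highest counts being without control replicate 3. The replicate numbers cannot be checked as pairs with 2 pairs, and the labels do not say that they mark a shared litter or day. Deviations from the group means correlated at 0.281 and 0.296 across genes for same-numbered samples, values that the group of 2 mirrors with the sign turned for the other pairing. With the replicate block, which leaves 1 residual degree of freedom, 552 genes were higher and 574 lower, and 12 lists were called. Replicate 3 occurs only as a control, so under the block this library adds nothing to the group difference. The comparison with the block rests on replicates 1 and 2 of each group. Lists called by camera there but not in the main test were distal luminal (adjusted p = 2.9e-17), androgen response (0.00116), T and B cell (0.00027), erythroid (0.00281) and interferon response genes (0.0202), all lower. Fibroblast and matrix (0.000214) and smooth muscle genes (0.00151) were higher.

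The number of lists called was 5 in the main test and ran from 4 to 11 when 1 library was left out, with 11 without control replicate 3 and 8 without Ghr deletion replicate 2. It was 12 with the seminal vesicle covariate, under which proliferation was called lower and the basal, adipocyte and mitochondrially encoded calls were lost. The seminal vesicle value of 0.0844 under it says nothing, since 4 of the 8 members make up the covariate. The other values under it are uncertain too, since these 4 genes each separate the groups. The number of lists called was 0 with an estimated correlation and 0 with fry. DESeq2 has no list test. The basal call had an adjusted p of 0.723 on log2(TPM + 1) and 0.118 on log2(TPM + 0.1), the adipocyte call 0.743 on log2(TPM + 1), the proliferation call 0.0864 with library size only, 0.91 (lower) on log2(TPM + 1) and 0.0516 on log2(TPM + 0.1), and the mitochondrially encoded call 0.0894 with library size only, 0.0394 (higher) on log2(TPM + 1) and 0.986 on log2(TPM + 0.1).

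The Ghr log2 fold change ran from -0.20 to 0.88 when 1 library was left out, and was -0.14 with the seminal vesicle covariate. Igf1 ran from -0.10 to 0.93, the lowest without Ghr deletion replicate 1. On log2(TPM + 1) and log2(TPM + 0.1), in that order, where the median of all genes was 0.87 and 1.33, values above 0 were Entpd2 at 0.32 and 0.38, Dok1 at 0.26 and 0.38, Krt5 at 0.77 and 0.88, mt-Nd3 at 0.70 and 0.70, mt-Atp6 at 1.00 and 1.01, Cldn3 at 0.68 and 0.71, Stat5b at 0.51 and 0.57, Stat5a at 0.55 and 0.58, Igf1r at 0.92 and 0.98, and Homer2 at 0.42 and 0.59. With library size only, where that median was 0.58, Krt5 was 0.045, mt-Atp6 0.12 and Igf1r 0.10. With the seminal vesicle covariate, Igf1 was -0.13, Svs6, itself part of the covariate, 0.59, Cidec -0.15, Tyms -0.30, Bub1 -0.72, Msmb 5.90, Azgp1 1.54, Epcam -0.0098, Krt7 0.54, Stat5b 0.16, Stat5a 0.17, Igf1r 0.069 and Igfbp7 -0.27. Msmb was 2.19 without control replicates 1 and 2 together. Relative to the median of all genes, 8 of 10 of these genes stayed lower on log2(TPM + 1), 10 of 10 on log2(TPM + 0.1) and 3 of 3 with library size only. The shift of all genes accounts for the signs of the genes that stayed lower. It does not for mt-Atp6 and Igf1r on log2(TPM + 1), which lay above that median by 0.14 and 0.056. No value listed passed the threshold, and for the other sign changes the cause was not tested. Among the other values of named genes, 583 under planned settings and 100 under added ones kept direction and side of the threshold, and 71 planned values kept direction and passed it. Depth in protein-coding genes ran from 14414303 to 34681131 counts. Of simulated 4-fold changes over 18330 genes, drawn independently at a mean of at least 2 CPM, 36% were called.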

Other observations

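All tests below were chosen after the results they bear on had been seen. This includes the division of the 5 libraries, since a count of 0 called genes fixed its outcome.

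Other genes, chosen after their values were seen, also divided the controls. Crisp1, a secretory protein best known from the epididymis, had 0.185, 2.72 and 866 CPM in the controls and 217 and 831 CPM in the libraries labelled Ghr deletion. Clu, clusterin, had 267, 183.1, 2368, 6193 and 1874 CPM in that order. Sva had 6517, 3955, 26.3, 0.318 and 1.26 CPM. Tgm4, a prostate transglutaminase, had 17.9, 1604, 2.93, 0.749 and 162 CPM, and the neuronal filament gene Prph 0, 38.7, 0.287, 0.204 and 3.68 CPM.

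Transcripts typical of liver were examined with 42 genes, the complete set looked up when low levels of Serpina3k and Gc were first noticed, so the count below was made on genes whose values had been seen. Of these, 26 were lower in both libraries labelled Ghr deletion than in all controls and 1 was higher, where chance gives 10% in each direction and the genes are not independent. Alb had 7.16, 24.0 and 6.64 CPM in the controls and 2.2 and 0.177 CPM in the libraries labelled Ghr deletion, and Serpina3k had 0.802, 4.32, 1.68, 0.0681 and 0 CPM. No explanation was tested.

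The mean of Ghr was not lower in the libraries labelled Ghr deletion, although the 95% interval of its log2 fold change, -0.42 to 1.3, includes a decrease. A swap of labels between the groups needs a control with low Ghr, set as 0.5 or less of the mean of the other controls. In CPM the lowest control held 0.81 of that mean. In TPM the controls held 1.44, 0.79 and 2.8, and the libraries labelled Ghr deletion 8.18 and 3.12. The spread among the controls thus depends on the scale. Counts over the whole gene also need not show a deletion, so these values do not decide on a swap. Scaling between libraries stays open, because the lowest log2 fold change over 3 other scalings was 0.43, but the median of all genes was -0.010 with RLE, 0.019 with upper-quartile factors and 0.58 with library size only, so none of them could have lowered Ghr by much. It also remains open that the rest of the gene may still be counted after a short exon is lost, or that few cells recombined, and neither was tested, because the counts are per gene.

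Of 8 seminal vesicle genes, 6 were lower in both libraries labelled Ghr deletion than in each control, and Svs2 and Pate4 were not. Scaling between libraries is argued against by a median of -6.74 with library size only. One share of seminal vesicle tissue stays open, because the 8 log2 fold changes spanned 12.4, but 4 members held 1433 CPM or more in every library, which could hide such a share, and the other 4, picked on those levels, spanned 2.00. An effect of Ghr deletion stays open, because 1 control library, control replicate 3, had a list mean nearer the deletion-labelled mean than that of the other controls, and 1 library decides nothing. A different mixture of several accessory glands in each dissection may also account for it and was not tested.

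The 6 genes with the smallest p are near-identical copies of abundant genes, at 98.7% to 100% identity, and DESeq2 called all 6. Reads shared with the matching gene could produce this, and in 3 of 6 pairs the match moved opposite to the copy by at least as much. Eif3j1 moved by -25.0 CPM where Eif3j2 moved by 19.2 CPM, Ahcy by -18.2 where Gm4737 moved by 7.46, and Rplp0 by -198 where Gm8730 moved by 6.77. Each match fell by more than its copy gained, most for Rplp0. Rplp0 had 518, 463 and 476 CPM in the controls and 316 and 259 CPM in the libraries labelled Ghr deletion. Shared reads would not make up its whole fall. The controls ran from 58.8 to 91.7 CPM for Eif3j1 and from 31.3 to 51.5 CPM for Ahcy, so for these the remainder is not decided. In the pairs of Gm7292, Rbpj-ps3 and Rpl15-ps3 the match varied too much between libraries to decide. A group difference in genetic background on chromosome 2, where 3 of the 6 matches lie, was examined after rates of small p had been looked at for every chromosome, and it has the highest rate of the 20 tested. With the copies and matches left out, 13 of 1396 genes there and 65 of 17138 elsewhere had separated groups and a p under 0.01 (Fisher's exact test, two-sided, p = 0.00745, adjusted p = 0.149 over 20 chromosomes), so the data do not decide it. The copies lie on chromosomes 6, 8, 9, 16 and 18, so this test does not bear on a background difference at the copies. Only the mice labelled Ghr deletion carried Cre at the ROSA26 locus. A background difference linked to Cre therefore cannot be told apart from the group and was not tested. No biological explanation was tested.

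Of the 10 splits of the 5 libraries into 3 and 2, all 10 gave at least the real count of 0 called genes, and the highest other split gave 623. With 10 splits no share under 0.05 can be reached. The split with 623 genes sets control replicates 1 and 2 against the other libraries, which points to a structure of the samples that the groups do not follow.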
